A study of Homo sapiens with 10 samples.

How the data were processed

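Single T cells from bronchoalveolar lavage, a wash of the airspaces, were profiled in 2 lung transplant recipients, called patient A and patient B. Each of the 10 plates (4 of patient A, 6 of patient B) held 96 wells with a sorted CD3+ cell each, and the wells were pooled for sequencing of poly(A) RNA with unique molecular identifiers (UMIs). The authors deposited raw UMI counts per feature and well, 56470 features in 960 wells, with no normalization. Reads were processed with STAR 2.5, Subread featureCounts 1.6 and UMI-tools on GRCh38, per the submitters' processing notes. The annotation release, the library kit, the strand setting and any cell filter applied before deposit are not given in the sources used here. A deposited table per well gave the origin of the cell (donor or recipient), its CD4 or CD8 class and its CD69 and CD103 level as low, intermediate or high. How origin and these levels were assigned is not given in the sources used here.

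The deposited counts were used as they stand. A cell entered if it had at least 500 UMIs, which kept 823 of the 960 wells. No doublet caller was run, since each well was meant to receive a single sorted cell. Counts were summed over cells of the same plate, CD4 or CD8 class and level compared, and a sum needed at least 3 cells. The CD103 sums were also kept apart by origin, and the CD8 against CD4 sums were taken per plate, origin and class. Sums, not cells, were the units of every test, and levels are given as CPM, the UMIs of a gene per 1e6 UMIs of the sum. The sums ranged from 2031 UMIs in the CD69 comparison to 98023 UMIs in the origin and class comparisons, so that only abundant transcripts could be tested singly.

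Each comparison was fitted with edgeR 4.0.16 (quasi-likelihood F test, TMM scaling, filterByExpr on the levels compared with a count minimum of 10 and a total of 15). Plate was a block, because both levels of a comparison came from the same plates, and CD4 or CD8 class was a covariate (origin as well for CD103, and origin in place of class for CD8 against CD4). Adjusted p-values are Benjamini-Hochberg values, with 0.05 as the threshold, and the SE of a log2 fold change was taken from the fold change and its F statistic. With plate as a block, the p-values measure the spread of sums within plates, where several sums of a plate enter as separate units. The plates came from only 2 patients, so the p-values carry no estimate of the spread between patients. Pairs join both levels within a plate and class, or within a plate and origin for CD8 against CD4. CD103 pairs were also kept apart by origin. A plate could therefore give several pairs. The pairing rests on plates that hold both levels: 7 for donor against recipient, 6 in its CD69+ subset, 7 for CD69, 6 for CD103 and 10 for CD8 against CD4. Plates 3 and 4 of patient A held donor cells only. On its plate 1 the UMI minimum kept 1 of 30 donor wells and 29 of 41 recipient wells. On its plate 2 the minimum kept 8 of 16 and 57 of 80. Within patient A the origins of the cells used thus stood mostly on different plates. For donor against recipient, also within CD69+ cells, and for CD69, patient A fitted alone had no plate block.

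High CD69 or CD103 was taken as positive and low as negative, and intermediate cells were left out. The planned comparisons had assumed positive and negative classes only, and this reading of the 3 levels was fixed before any test was run. Left out of all tests were 449 sex-linked features, 18 polymorphic HLA genes, 14 genes in common deletions and 548 antigen receptor segments, which together held 0.739% of UMIs. Features with clone names or annotated as pseudogenes held 44.2% of all UMIs. Genes that share sequence with such features are therefore uncertain in level. They include TMSB4X with its copies TMSB4XP4 and TMSB4XP8, FTL, the mitochondrial genes with their nuclear copies, and HNRNPA1P40. A few features that were present or absent by origin in opposite ways in the patients resembled person-specific sequence and are not named.

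Genes were named by a rule fixed with the comparisons, the gene lists, the marker lists and the other settings before the data were examined. Among genes past the threshold with the same sign in each patient fitted alone, the 12 with the smallest p per direction were named. Always named were CD4, CD8A, CD8B, CD69, ITGAE, S1PR1, KLF2, CXCR6 and ITGA1. Up to 4 members per gene list were added if they passed. Gene positions are from GENCODE release 29 on GRCh38, matched by symbol.

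The 18 gene lists covered tissue residency (higher and lower), cytotoxicity, cytokines and chemokines, inhibitory receptors, naive and central memory cells, cell cycle, interferon response, immediate early and NF-kB genes, heat shock, activation, adhesion and chemotaxis, regulatory T cells, type 17 cells, glycolysis, lipid metabolism, mitochondrial transcripts and ribosomal proteins. The 12 marker lists covered alveolar macrophages, monocytes, B and plasma cells, epithelium, NK cells, mast cells, dendritic cells, erythroid cells, unconventional T cells, CD4 T cells, CD8 T cells and T cells. Lists were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, and again with an estimated correlation and with fry. List members needed at least 30 UMIs over the sums, and a list needed at least 3 such members.

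Several choices were made after seeing the data. The filter for single genes left 122 to 471 genes per comparison and excluded most list members, so a second edgeR fit took all genes with at least 30 UMIs at the TMM factors of the planned filter. Lists were also tested as the sum of their members' UMIs, entered as a feature of the edgeR fit, which covers lists with few measured members. TMM factors taken from all genes with at least 30 UMIs were first used for the second fit and for camera. They were replaced because shallow sums lose many genes with 0 counts from that calculation, and they are kept as an alternative. Fits without pseudogenes and clone-named features, and with intermediate cells counted as positive, were added too. The settings varied from the start were DESeq2 1.42.0, RLE scaling, library size only, no gene filter, other UMI and cell minimums, cells thinned to 500 UMIs, sums over both classes, no plate block, sums per patient, each patient or class alone, CD69+CD103+ cells only, recipient cells only, and leaving out each plate.

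Shares of cells were compared between donor and recipient cells of the same plate with exact two-sided permutation tests that flip the signs of the plate differences. Intervals of shares are 95% Wilson intervals and cover counting error only. The fitting steps were tested on simulated counts with the real depths, an assumed dispersion of 0.1 and no differences between plates, patients or classes. The recovered shares hold for that setting and were not measured on the real spread. For donor against recipient, 100% of the 4-fold changes among the genes tested (15 genes) and 70% of those of 2-fold (10 genes) were recovered, with 1 false call. For CD103 the recovered shares were 100% of 13 genes and 33.3% of 3 genes. Analyses ran in R 4.3.3 and Python 3.11.15.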

Results

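T cells in the airspaces of a transplanted lung come from the donor, carried over with the graft, or from the recipient, who repopulates it. The series asks how resident memory T cells arise and persist in this setting. Resident memory cells stay in tissue and are usually recognised by the surface proteins CD69 and CD103 (the integrin encoded by ITGAE). The deposited wells allow 4 questions: how donor cells differ from recipient cells, how CD69+ differ from CD69- cells, how CD103+ differ from CD103- cells, and how CD8 differ from CD4 cells.

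The 10 plates held 1212693 UMIs in all, from 64113 (patient A, plate 2) to 160817 (patient B, plate 3). The 823 cells with at least 500 UMIs had a median of 1315 UMIs and 899 genes. Median depth was higher in patient B than in patient A, at 1569 and 1455 UMIs per donor and recipient cell against 1168 and 904. Of these cells 405 were classed as CD8 and 234 as CD4, with known origin. A further 164 had an origin but no class, and 20, on plate 1 of patient A, had neither. At this depth CD4 mRNA gave 18 UMIs in CD4 cells, and S1PR1, whose receptor draws T cells out of tissue, gave 1 UMI in all the cells compared.

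Among cells with a class, donor T cells were mostly CD8 cells, whereas recipient T cells held a larger share of CD4 cells. Of cells with a class, 94.2% of donor cells in patient A (145 of 154, 95% Wilson interval 89.3 to 96.9) and 81.1% in patient B (99 of 122, 73.3 to 87.1) were CD8. Among recipient cells the shares were 65.4% (51 of 78, 54.3 to 75.0) and 38.6% (110 of 285, 33.1 to 44.4). In patient B 285 of 399 recipient cells and 122 of 157 donor cells had a class. The cells with no class resembled CD8 cells more than CD4 cells in their transcripts. Counted as CD8 they would raise the recipient shares more than the donor shares and narrow the gap. CD103+ cells made up 82.6% of donor and 33.7% of recipient cells in patient A, and 42.0% against 32.3% in patient B. CD69+ cells made up 42.2% against 17.4% in patient A and 60.5% against 51.1% in patient B.

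Across the 7 plates with at least 3 cells of each origin, 6 of them from patient B, the CD8 share was 39.9 ± 10.4 percentage points higher in donor cells (SD, n = 7, higher on 7 plates). The exact permutation p was 0.0156, the smallest possible with n = 7, and 0.0234 after adjustment over the 3 shares. The CD103+ share was 16.2 ± 18.0 points higher (SD, n = 7, higher on 7 plates, exact permutation p = 0.0156, adjusted 0.0234). For CD69 the difference was 10.8 ± 12.2 points (SD, n = 7, higher on 5 plates), which did not pass, with an exact permutation p of 0.0625. Within CD8 cells the CD103+ share differed by 0.18 ± 22.5 points (SD, n = 7, exact permutation p = 0.984) and the CD69+ share by -1.5 ± 23.3 points (exact permutation p = 0.859). These means join opposite directions. Among CD8 cells of patient A, over all plates, 87.6% of donor cells (127 of 145) and 47.1% of recipient cells (24 of 51) were CD103+, and in patient B 54.5% (54 of 99) and 62.7% (69 of 110). For CD69+ the shares were 42.8% and 15.7% in patient A and 64.6% and 69.1% in patient B. In patient A the origins stood mostly on different plates. Without plate 2 of patient A the CD103 difference was 9.86 points. With no minimum of UMIs the CD103 difference was 9.76 points (8 plates, exact permutation p = 0.0625) and the CD8 difference 28.0 points (8 plates, exact permutation p = 0.0547). Shares describe the sorted wells, which the sort may have shaped, and the CD8 shares leave out the cells with no class.

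**Figure D1:**
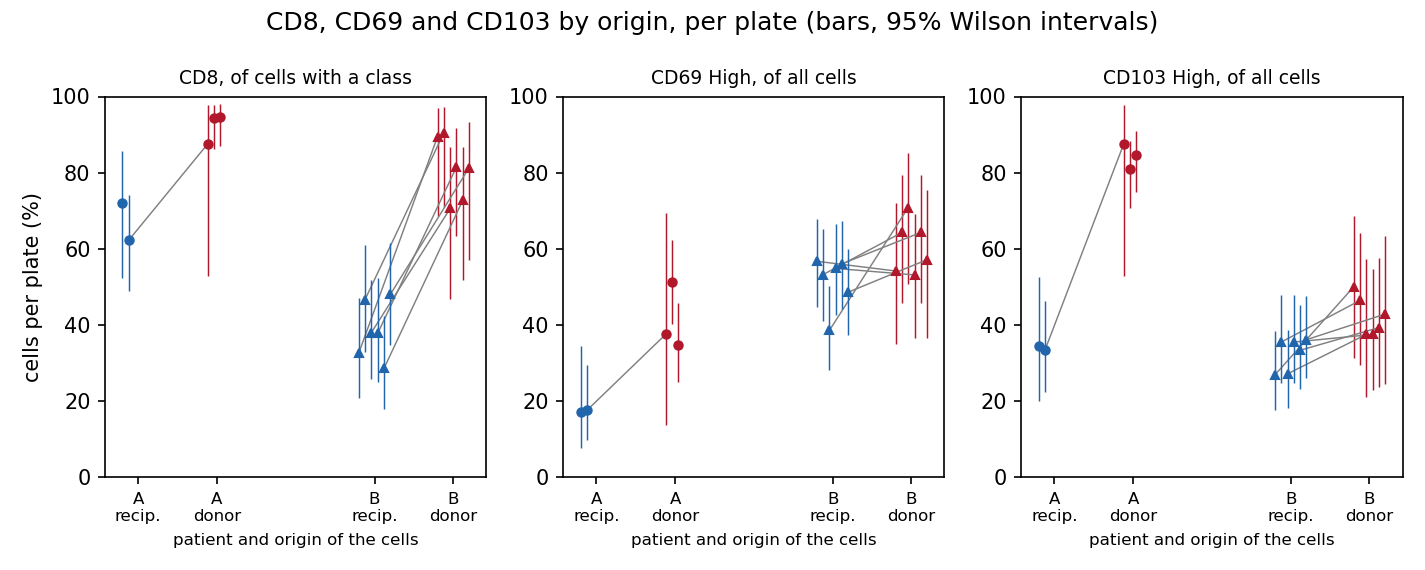
Percentage of cells that were CD8 (of cells with a class), CD69 high and CD103 high, per plate, in recipient (blue) and donor (red) cells of patient A (circles) and patient B (triangles). Bars are 95% Wilson intervals and grey lines join cells of the same plate; the CD8 share was higher in donor cells on each of the 7 joined plates.

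Donor T cells carried more RNA of cytotoxic effector genes than recipient T cells of the same plates and class. GZMB, which encodes the killing protease granzyme B (chromosome 14, 24630954 to 24634267), was 2.22-fold higher in donor cells. Its level was 1381 ± 959 CPM in donor sums and 727 ± 549 in the paired recipient sums (SD, n = 11 pairs, higher in 8). CCL5, a chemokine of effector and memory T cells (chromosome 17, 35871491 to 35880793), was 1.56-fold higher, at 3824 ± 2250 against 2735 ± 1898 CPM (higher in 8 of 11 pairs). CD52, a surface glycoprotein of lymphocytes (chromosome 1, 26317957 to 26320523), was also higher (2558 ± 666 against 1807 ± 520, higher in 11 of 11 pairs).

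The edgeR test compared 15 donor sums (270 cells) with 16 recipient sums (363 cells). Of 443 genes tested, 7 were higher and 1 lower in donor cells at an adjusted p under 0.05, and 46 had an unadjusted p under 0.05. The log2 fold change in edgeR was 1.15 ± 0.25 for GZMB (SE, adjusted p = 0.0071), 0.59 ± 0.14 for CD52 (adjusted p = 0.019) and 0.64 ± 0.17 for CCL5 (adjusted p = 0.036). CCL5 lost its call in 19 of 29 other settings, with values from 0.06 to 1.01, and CD52 in 15 of 29, reversing in 1 more. Fitted alone, GZMB was higher by 0.80 in patient A and 1.30 in patient B. The value of patient A came from comparing different plates: on plate 2, its only plate with sums of at least 3 cells of both origins, donor CD8 cells were lower than recipient CD8 cells (1682 against 2280 CPM). DNMT3A, a DNA methyltransferase, also passed (1.22 ± 0.32, edgeR adjusted p = 0.040, higher in 9 of 11 pairs). Its level in patient A rested on plate 4, at 3710 CPM against 313 to 581 on the other plates. That plate held donor cells only, so it bears on patient A fitted alone and adds no comparison of origins to the blocked fit. Without plate 4 of patient B DNMT3A stood at 0.85, its lowest value with a plate left out. It lost its call in 20 of 29 other settings, with values from 0.61 to 1.79. The other genes past the threshold had opposite signs in the patients fitted alone and were named after their values were seen. In patient A that fit again compared mostly different plates. They were TMSB4X, which encodes an actin-binding peptide (0.62 ± 0.10), its pseudogenes TMSB4XP4 and TMSB4XP8, and ALOX5AP, which encodes an activator of leukotriene synthesis (-0.99 ± 0.25, edgeR adjusted p = 0.025). ALOX5AP was lower in 11 of 11 pairs, which came from 7 plates. On plate 2 of patient A the pair was nearly level (1513 against 1520 CPM).

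**Figure D2:**
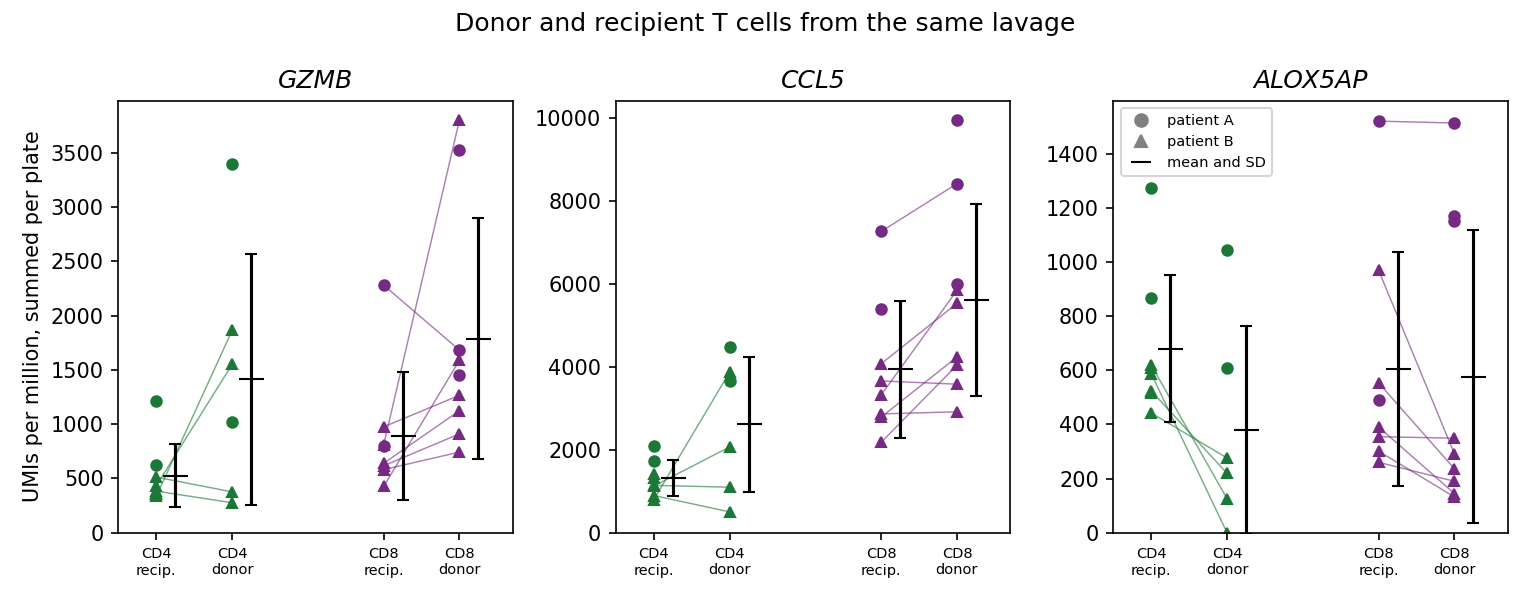
CPM of GZMB, CCL5 and ALOX5AP in sums of cells per plate, by class and origin, for patient A (circles) and patient B (triangles), with the mean and SD per group. Lines join sums of the same plate; GZMB averaged 1788 CPM in the 9 donor CD8 sums and 891 in the 8 recipient CD8 sums.

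As a group, cytotoxicity genes rose in donor cells. Of 11 measured members 10 had positive log2 fold changes, with a median of 0.78 (camera adjusted p = 0.00059, and adjusted p = 0.0097 with an estimated correlation). In edgeR GZMB passed over all genes tested, and 4 members passed adjusted over the list alone. These were GZMB, GNLY (granulysin, a pore-forming protein, 1.12 ± 0.35), KLRD1 (an NK receptor subunit, 1.38 ± 0.45) and NKG7 (a granule protein, 0.75 ± 0.28). The summed UMIs of the list were 1.75-fold higher (log2 0.81 ± 0.17, edgeR adjusted p = 0.00062). Heat shock genes were higher in all 8 measured members, with a median of 0.75 (camera adjusted p = 0.0010, adjusted p = 0.065 with an estimated correlation), and their summed UMIs rose by log2 0.74 ± 0.19 (edgeR adjusted p = 0.0034). HSPA1A, which encodes an inducible chaperone, passed in the fit of genes with at least 30 UMIs (2.38 ± 0.62, edgeR adjusted p = 0.044). In patient A alone, whose origins stood mostly on different plates, it was lower in donor cells. HSPA1A was the only member to pass over all genes and over the list alone. Cytokine and chemokine genes had a median of 0.61 (camera adjusted p = 0.050, adjusted p = 0.22 with an estimated correlation and 0.16 with TMM factors from more genes). CCL5 was their only member to pass, over all genes and adjusted over the list alone, and the summed UMIs did not pass (log2 0.27 ± 0.11, edgeR adjusted p = 0.093).

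Ribosomal protein genes ranked lower than other genes (camera adjusted p = 2.7e-05, adjusted p = 0.010 with an estimated correlation), although the median and mean of their 79 members were 0.03 and 0.01. Their summed UMIs differed by log2 0.04 ± 0.04 (edgeR adjusted p = 0.37). Of the genes higher in resident cells, ZNF683, which encodes the transcription factor Hobit, passed in the fit of genes with at least 30 UMIs (1.88 ± 0.47, edgeR adjusted p = 0.035, same sign in each patient). As a sum that list differed by log2 0.18 ± 0.17 (edgeR adjusted p = 0.38). The genes lower in resident cells differed by -0.45 ± 0.35 (edgeR adjusted p = 0.34).

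Other residency genes did not pass in that fit: CXCR6, an airway homing receptor, at 0.71 ± 0.32 (edgeR adjusted p = 0.60), ITGA1, the collagen-binding integrin CD49a, at 0.99 ± 0.57, ITGAE at 0.75 ± 0.46 and CD69 at 0.62 ± 0.44. CD8A and CD8B were at 0.18 ± 0.30 and -0.43 ± 0.38. KLF2, a transcription factor of circulating T cells, and CD4 each gave only 4 donor and 16 recipient UMIs. In the other lists the summed UMIs did not pass in edgeR. The log2 differences were 0.51 ± 0.19 for interferon response (adjusted p = 0.071, with 5 of 12 members higher adjusted over the list alone and 0 over all genes), 0.36 ± 0.15 for naive and central memory genes (0.093), 0.35 ± 0.17 for immediate early and NF-kB genes (0.13) and 0.33 ± 0.17 for glycolysis (0.14). Regulatory T cell genes stood at -0.83 ± 0.42 (edgeR adjusted p = 0.14), inhibitory receptors at -0.22 ± 0.28, lipid metabolism at 0.52 ± 0.35 and adhesion and chemotaxis at 0.13 ± 0.20. Activation genes stood at 0.16 ± 0.10, cell cycle at 0.10 ± 0.30, type 17 genes at 0.04 ± 0.40 and mitochondrial transcripts at 0.08 ± 0.06.

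Marker lists of other cells did not pass between origins. NK cell markers had the smallest p (95 against 29 UMIs, log2 1.16 ± 0.46, edgeR adjusted p = 0.22). The sums of alveolar macrophage (0.07 ± 0.19), monocyte (-0.74 ± 1.01), B and plasma cell (-0.76 ± 0.90) and epithelial markers (-1.31 ± 0.82) had edgeR adjusted p-values from 0.77 to 0.87. Pooled ratios, which mix plates and classes, can differ from these values. Epithelial markers pooled were higher in donor cells (38 against 20 UMIs, log2 1.37, 95% interval 0.55 to 2.23) and monocyte markers lower (4 against 23 UMIs). Mast cell, dendritic cell and erythroid markers gave 7, 2 and 9 UMIs in all. CD4, CD8 and general T cell markers differed by -0.07 ± 0.69, -0.05 ± 0.22 and 0.08 ± 0.11, and unconventional T cell markers by -0.31 ± 0.44 (pooled log2 0.77, 102 against 81 UMIs).

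These calls came mainly from patient B: edgeR called 8 genes in patient B alone, and in patient A alone 0 genes, with 13 at an unadjusted p under 0.05. TMM factors from all genes with at least 30 UMIs moved the median fold change by -0.40 and left 1 gene (ALOX5AP); relative to that scaling GZMB stood at 0.71 (edgeR adjusted p = 0.079). There the cytotoxicity sum (0.36 ± 0.21, edgeR adjusted p = 0.26) and the heat shock sum (0.30 ± 0.21, adjusted p = 0.36) lost their calls, while 11 of the 15 positive list sums turned negative, among them cytokines (-0.22), higher residency genes (-0.28), activation (-0.31), naive and central memory genes (-0.09), immediate early and NF-kB genes (-0.11) and glycolysis (-0.10). Lower in donor cells at an edgeR adjusted p under 0.05 were then regulatory T cell genes (-1.29), ribosomal proteins (-0.45) and mitochondrial transcripts (-0.41). Under library size alone 4 sums turned negative, including mitochondrial transcripts (-0.01) and ribosomal proteins (-0.05). Without patient B's plate 1 the count fell to 4, and without plate 3, 4 or 6 to 5; without plate 3 GZMB stood at 0.90 (edgeR adjusted p = 0.10). In edgeR no gene passed for a change of its origin difference with class (0 of 443, with 23 at an unadjusted p under 0.05) or with patient (0, with 36). The test by patient cannot decide whether the patients agree, since in patient A only plate 2 held sums of both origins.

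Within CD69+ cells donor and recipient cells differed in the same direction for GZMB, which was 2.56-fold higher in donor cells. The level was 1633 ± 1209 against 587 ± 232 CPM (SD, n = 10 pairs, higher in 8). TMSB4X was 1.41-fold higher (11100 ± 2181 against 7769 ± 1406 CPM, higher in 10 of 10 pairs). This comparison asks whether the origins differ at the same CD69 level, from 12 donor sums (136 cells) and 14 recipient sums (164 cells). The 6 plates with sums of both origins were all of patient B. All pairs thus came from patient B, and patient A gave no comparison of origins within a plate.

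Of 239 genes tested, edgeR called 5, all higher in donor cells, against 22 at an unadjusted p under 0.05. They were DNMT3A (1.56 ± 0.33), TMSB4X (0.50 ± 0.11), TMSB4XP4 (0.49 ± 0.12), GZMB (1.36 ± 0.32), each with an edgeR adjusted p of 0.021, and TMSB4XP8 (0.56 ± 0.15, adjusted p = 0.043). The thymosin genes share sequence and count as a single signal. Cytotoxicity genes rose as a group (9 of 10 positive, median 0.49, camera adjusted p = 0.00034, adjusted p = 0.022 with an estimated correlation; summed UMIs log2 0.86 ± 0.22, edgeR adjusted p = 0.011). GZMB and GNLY (1.79 ± 0.49) passed adjusted over the list alone, and GZMB over all genes. Cytokine and interferon genes had medians of 0.58 and 0.52 (camera adjusted p = 0.021 and 0.024, and adjusted p = 0.12 for each with an estimated correlation). Ribosomal protein genes had a median of -0.09 (camera adjusted p = 0.016, adjusted p = 0.12 with an estimated correlation). No member of these last lists passed, over all genes or adjusted over the list alone. CXCR6 stood at 0.62 ± 0.39, ITGAE at 0.89 ± 0.61, CD69 at -0.04 ± 0.54, CD8A at 0.19 ± 0.37 and CD8B at -1.31 ± 0.51 (edgeR adjusted p = 0.47). ITGA1, CD4, KLF2 and S1PR1 gave 28, 14, 6 and 0 UMIs. NK cell markers gave 40 against 9 UMIs (within plates log2 0.91 ± 0.59, edgeR adjusted p = 0.72), although the sort for CD3 would remove NK cells, which lack it.

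With TMM factors from all genes with at least 30 UMIs the median moved by -0.16 and edgeR called 0 genes, GZMB standing at 1.18 (adjusted p = 0.097); the cytotoxicity sum then lost its call (0.67 ± 0.23, edgeR adjusted p = 0.073). Of the 9 positive list sums 5 turned negative: cytokines (from 0.14 to -0.04), activation (-0.19), adhesion and chemotaxis (-0.08), glycolysis (-0.05) and immediate early and NF-kB genes (-0.01). Thinned to equal depth 0 genes were called, and without patient B's plate 2, 3 or 5 the count was 2, 1 and 2; GZMB then lost its call without plate 3 (1.14), 4 (1.27) or 5 (1.13).

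CD69+ recipient cells had less ferritin light chain RNA and more IL32 and S100A4 RNA than CD69- recipient cells. FTL, which encodes part of the iron store ferritin (chromosome 19, 48965301 to 48966878), was 2.02-fold lower, at 726 ± 334 against 1526 ± 711 CPM (SD, n = 12 pairs, lower in 11). IL32, a cytokine gene of activated T cells (chromosome 16, 3065297 to 3082192), was 1.96-fold higher (1110 ± 483 against 688 ± 589 CPM, higher in 9 of 12 pairs). S100A4, a calcium-binding protein gene of effector and memory cells (chromosome 1, 153543613 to 153550136), was 1.88-fold higher (1187 ± 462 against 606 ± 401, higher in 9 of 12 pairs).

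CD69 is used as a mark of residency, and the comparison was made within recipient cells, with 14 CD69+ sums (164 cells) and 13 CD69- sums (110 cells). Of 170 genes tested edgeR called 4 higher and 1 lower, with 27 at an unadjusted p under 0.05. The log2 fold changes were -1.02 ± 0.22 for FTL (edgeR adjusted p = 0.014), 0.97 ± 0.24 for IL32 (0.019) and 0.91 ± 0.25 for S100A4 (0.033). TMSB4X (0.58 ± 0.14) and TMSB4XP4 (0.71 ± 0.16) were also higher, each in 11 of 12 pairs. All 5 had the same sign in each patient fitted alone, but patient A had few cells and its fit had no plate block. On plate 2, its only plate with sums of at least 3 cells at both levels, S100A4 was lower in CD69+ sums of both classes (706 against 992 and 725 against 750 CPM), and IL32 was lower in CD4 sums. The sign of S100A4 in patient A therefore rested on plate 1, which gave a CD69- sum only, at 133 CPM. Transcripts of CD69 itself gave 26 and 8 UMIs (0.41 ± 0.65). CXCR6 stood at 1.13 ± 0.56 (47 against 10 UMIs, higher in 9 of 12 pairs, edgeR adjusted p = 0.59), CD8A at 0.51 ± 0.57 and CD8B at 0.54 ± 0.64. ITGAE, ITGA1, CD4, KLF2 and S1PR1 gave 29, 14, 12, 12 and 1 UMIs.

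**Figure D3:**
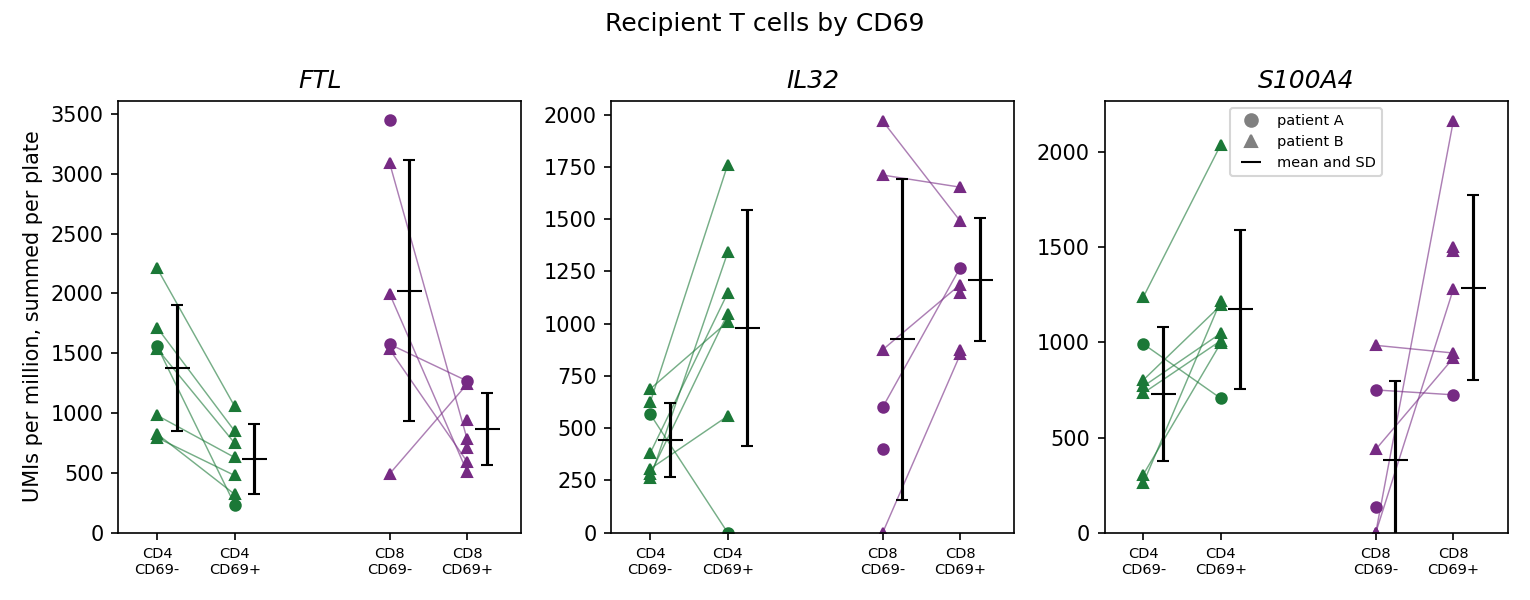
CPM of FTL, IL32 and S100A4 in sums of recipient cells per plate, by class and CD69 level, for patient A (circles) and patient B (triangles), with the mean and SD per group. Lines join sums of the same plate; FTL was lower in CD69+ sums in 11 of the 12 joined pairs.

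Of the 12 gene lists with enough members, 0 passed camera, the smallest adjusted p being 0.16, and fry gave 1 (naive and central memory genes, lower, adjusted p = 0.041). Among the summed lists the smallest p-values were those of regulatory T cell genes (1.11 ± 0.45, edgeR adjusted p = 0.26), inhibitory receptors (0.80 ± 0.38, 0.26) and immediate early and NF-kB genes (0.51 ± 0.22, 0.26). The alveolar macrophage markers were lower as a sum (225 against 221 UMIs at unequal depth, log2 -0.94 ± 0.21, edgeR adjusted p = 0.0016). FTL supplied most of that sum, and without FTL and CTSD the other 12 markers gave 6 against 16 UMIs (-0.59 ± 0.81, edgeR adjusted p = 0.68). NK cell markers stood at -2.09 ± 0.77 (9 against 13 UMIs, edgeR adjusted p = 0.083) and monocyte markers at -1.78 ± 0.98 (4 against 11 UMIs, edgeR adjusted p = 0.19).

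In CD8 cells alone edgeR called 0 genes (FTL -0.96, IL32 0.57), and with patients as the units also 0 (FTL -0.92), with 34 at an unadjusted p under 0.05. Cells with at least 1000 UMIs gave an FTL difference of -0.61 (edgeR adjusted p = 0.11), and without patient B's plate 4 the count fell to 1, without plate 3 FTL stood at -0.80 (adjusted p = 0.060).

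Among CD69+ cells no gene abundant enough for the planned filter passed between CD103+ and CD103- cells. The comparison asks what CD103 adds to CD69 and held 17 CD103+ sums (157 cells) and 14 CD103- sums (84 cells). Of 122 genes tested edgeR called 0, with 7 at an unadjusted p under 0.05, and DESeq2 also called 0, with 10. ITGAE transcripts, which encode CD103 itself, stood at 1.68 ± 0.91 (33 against 5 UMIs, higher in 5 of 8 pairs, edgeR adjusted p = 0.99), and CD69 at 1.67 ± 0.79 (43 against 7 UMIs, higher in 6 of 8 pairs). CXCR6 stood at -0.08 ± 0.55, CD8A at -0.06 ± 0.42 and CD8B at -0.23 ± 0.61. ITGA1, CD4, KLF2 and S1PR1 gave 25, 12, 5 and 0 UMIs.

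No list passed camera, with a smallest adjusted p of 0.19. Adjusted over the list alone, 3 of the 8 measured cytokine genes were higher in CD103+ cells, and over all genes 0: TNF (2.90 ± 0.98), CCL5 (0.64 ± 0.22) and CCL4 (1.06 ± 0.42). The type 17 genes had the smallest p among summed lists (2.06 ± 0.65, edgeR adjusted p = 0.075). Fewer than 3 members of that list reached 30 UMIs. RORA, given next, is among them, so the sum and RORA are not separate results. The fit of genes with at least 30 UMIs called 2 genes, of which RORA, a transcription factor of type 17 cells and chosen after its values were seen, stood at 2.23 ± 0.51 (edgeR adjusted p = 0.044). In the fit with the planned filter RORA did not pass (2.25 ± 0.80, edgeR adjusted p = 0.58).

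CD8 cells differed from CD4 cells in cytotoxic and chemokine genes and in mitochondrial transcripts, and their CD8 transcripts followed the deposited class. CCL5 was 2.80-fold higher in CD8 cells, at 4443 ± 2096 against 1870 ± 1248 CPM (SD, n = 14 pairs, higher in 13). GZMA, which encodes granzyme A (chromosome 5, 55102648 to 55110252), was 2.24-fold higher (622 ± 256 against 325 ± 212, higher in 12 of 14 pairs). CCL4, a chemokine of activated CD8 cells, was 2.17-fold higher (675 ± 426 against 375 ± 326, higher in 12 of 14 pairs). CD8A was 5.63-fold and CD8B 12.5-fold higher, and CD4 gave 2 UMIs in CD8 and 18 in CD4 cells.

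The test held 17 CD8 sums (404 cells) and 14 CD4 sums (229 cells). Of 471 genes edgeR called 14, all higher in CD8 cells, with 69 at an unadjusted p under 0.05, and 13 had the same sign in each patient. The log2 fold change was 1.49 ± 0.15 for CCL5 (edgeR adjusted p = 1.6e-08), 1.16 ± 0.22 for GZMA (adjusted p = 0.00096) and 1.12 ± 0.28 for CCL4 (adjusted p = 0.019). STK17B, an apoptosis-related kinase gene, stood at 0.93 ± 0.20 (edgeR adjusted p = 0.0042) and MT-ATP6, a subunit gene of ATP synthase, at 0.68 ± 0.15 (adjusted p = 0.0050). MT-CO2 (0.41 ± 0.11), MT-CO3 (0.53 ± 0.14) and MT-CO1 (0.47 ± 0.13), subunit genes of cytochrome c oxidase, passed too, as did the nuclear copies MTATP6P1 (0.84 ± 0.19) and MTCO2P12 (0.68 ± 0.17). The call was lost in 21 of 26 other settings for MT-CO2, 20 of 26 for MT-CO3 and 15 of 24 for MTCO2P12. For MT-ATP6 it was lost in 5 of 26 and for MTATP6P1 in 5 of 24. Uncertain in identity were the pseudogene HNRNPA1P40 (1.90 ± 0.25) and the clone-named RP11-846F4.6 (0.61 ± 0.16). ANGPT1 (2.26 ± 0.32), which encodes an angiogenic factor, also passed, and whether its reads belong to that gene was not tested. APOBEC3C, a cytidine deaminase gene named after its values were seen, was higher overall (0.79 ± 0.19) but lower in patient A alone.

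In the fit of genes with at least 30 UMIs CD8A stood at 2.49 ± 0.33 (edgeR adjusted p = 1.9e-08, higher in 14 of 14 pairs) and CD8B at 3.65 ± 0.46 (adjusted p = 7.5e-09). Cytotoxicity genes rose together, all 11 measured members being positive with a median of 1.15 (camera adjusted p = 2.0e-19, adjusted p = 1.5e-07 with an estimated correlation). Over all genes with at least 30 UMIs 4 passed in edgeR and 8 adjusted over the list alone, led by NKG7 (2.29 ± 0.31), CTSW (a granule protease, 2.45 ± 0.44), GZMA and KLRK1 (the activating receptor NKG2D, 2.84 ± 0.68). Of 10 cytokine genes 9 were positive (camera adjusted p = 2.1e-07, adjusted p = 0.0011 with an estimated correlation). Over all genes with at least 30 UMIs CCL5, CCL4 and XCL1 (2.25 ± 0.59) passed, and adjusted over the list alone 5 were higher and LTA lower (-1.36 ± 0.46). Mitochondrial transcripts were higher in all 13 members, with a median of 0.41 (camera adjusted p = 4.8e-17, adjusted p = 3.0e-05 with an estimated correlation). Of these, 4 passed over all genes with the planned filter, 1 over all genes with at least 30 UMIs, and 8 adjusted over the list alone. Their sum was 0.39 ± 0.05 at the planned scaling and 0.28 to 0.66 under the other scalings.

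Among marker sums CD8 T cell (2.92 ± 0.26, edgeR adjusted p = 4.2e-11), NK cell (1.65 ± 0.49, 0.0071), unconventional T cell (1.11 ± 0.40, 0.023) and T cell markers (0.36 ± 0.10, 0.0054) were higher in CD8 cells, and CD4 T cell markers lower (-2.09 ± 0.53, 0.0029). The NK and unconventional sums rested on few genes. In CD8 cells KLRC1 gave 98 UMIs, against 114 for all NK cell markers. TRGC1 and TRGC2 gave 142 of the 148 unconventional T cell UMIs. The other unconventional markers gave few UMIs in CD8 and CD4 cells: TRDC 3 and 6, SLC4A10 2 and 9, and ZBTB16 1 and 0. Of the always-named genes CD69 stood at 1.13 ± 0.45 (edgeR adjusted p = 0.44), CXCR6 at 0.63 ± 0.31 (0.65), ITGA1 at 0.78 ± 0.54 and ITGAE at 0.14 ± 0.40, with 20 KLF2 UMIs and 1 of S1PR1.

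TMM factors from all genes with at least 30 UMIs moved the median by 0.16 and raised the count to 34, while library size alone moved it by -0.11 and gave 8. Thinned to equal depth 1 gene was called, and leaving out plate 1 or 3 of patient A (8 each) or plate 1, 3, 4, 5 or 6 of patient B (6, 6, 6, 9 and 9) lowered the count. In edgeR no gene passed for a change of its class difference with origin or patient (0 of 471 for each, with 25 and 28 at an unadjusted p under 0.05). The smallest edgeR adjusted p was 0.23 by origin and 0.062 by patient.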

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

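The test of scaling for TMSB4X was chosen after its result was seen. The test of macrophage RNA for FTL was set out beforehand on markers summed over all plates, and the value within plates replaced it after the first result was seen. The other tests in this part were set out before their results were known.

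Depths, shares of cells and the levels of named genes were compared between plates of the same patient in 70 groups of plates. Of these 3 held a plate far from the others. Chance gives about 1 in 20, so these 3 are no more than chance would give. DNMT3A reached 3710 CPM on a plate of patient A, against 313 to 581 on the other plates. CD69 reached 175 CPM on a plate of patient A, against 56.1 to 70.4. IL32 stood at 793 CPM on a plate of patient B, against 964 to 1056. Some data outside the comparisons were flagged as well. On plate 1 of patient A, 20 cells with at least 500 UMIs had no origin given. The cells with an origin but no CD4 or CD8 class held 206 CPM of CD8B.

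Chance splits of the sums that swap the levels within plates seldom gave as many genes. For donor against recipient 1 of 64 splits, the real one, reached 8 genes, and the highest other gave 7. In CD69+ cells 1 of 32 reached 5, the highest other giving 1. For CD69 1 of 64 reached 5, the highest other giving 3. For CD8 against CD4 1 of 100 drawn splits reached 14, the highest other giving 8. In each of these 4 comparisons the real split alone reached its count, a share of splits under 0.05. The splits swap levels only on plates that hold both, which for origin were mostly of patient B, and in CD69+ cells all of patient B. They therefore cannot exclude chance differences between patients. For CD103 the real count was 0, so all 32 splits reached it, the highest giving 2.

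Higher GZMB in donor cells could reflect a few deep cells or other CD69 and CD103 levels, while the mix of CD4 and CD8 cells was held fixed by sums kept apart by class. Thinned to equal depth the log2 fold change was 0.91 ± 0.31 (edgeR adjusted p = 0.29), against 1.15 ± 0.25 before. Within CD69+CD103+ cells it was 1.06 ± 0.41 (adjusted p = 0.56). Each value stayed above 0.5 times the unrestricted one by more than its SE, which argues against each as the whole cause, although each value was lower, each SE was wider and both calls ended. GZMB also lost its call under TMM factors from more genes, so a part played by scaling stays open. A difference in cell state between donor and recipient cells may remain as a hypothesis. With plate as a block the value rests on plates that held both origins, mostly of patient B. In patient A only plate 2 held sums of both origins, so whether that patient shares the difference stays open.

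Lower FTL in CD69+ recipient cells could come from macrophage RNA in CD69- wells, since lavage is rich in macrophages, although the CD3 sort would remove whole macrophages. Summed over all plates, the other 12 macrophage markers gave 6 against 16 UMIs, a log2 ratio of -2.41 (95% interval -4.05 to -0.99), which by the criterion set beforehand goes with macrophage RNA. Within plates, the value chosen afterwards because the pooled ratio mixes plates, they changed by -0.59 ± 0.81, which cannot settle the question. Thinning left FTL at -1.30 ± 0.38 (edgeR adjusted p = 0.11, the call ending with a larger SE and a change no smaller). This argues against deep cells leading the sums. Thinning cannot test whether shallow cells hold a larger share of FTL. In cells with at least 1000 UMIs FTL stood at -0.61 and lost its call, so a part played by shallow cells stays open. Macrophage RNA and a difference between T cells cannot be told apart here.

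TMSB4X was higher in donor cells of both patients together but not in patient A alone, where the origins stood mostly on different plates. The lower of its values under library size and under TMM factors from more genes was 0.15 ± 0.17, against 0.62 ± 0.10, so scaling may account for it, and the error keeps this open. Thinned to equal depth it was 0.49 ± 0.13 (edgeR adjusted p = 0.12, the call ending), which argues against deep cells leading the sums. Its reads can fall on TMSB4XP4 and TMSB4XP8, and the design's biological alternative, donor origin itself, was not separated from scaling.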

How the results depend on the processing

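Added after seeing the data were the fit of genes with at least 30 UMIs, the fit without pseudogenes and clone-named features, TMM factors from more genes (also for camera, which again gave 11 lists, with mitochondrial transcripts, lower in donor cells, in place of cytokines), intermediate cells as positive, and summed list UMIs. The counts of genes were 8 for donor against recipient, 5 in CD69+ cells, 5 for CD69, 0 for CD103 and 14 for CD8 against CD4. DESeq2 gave 11, 5, 7, 0 and 21 genes in that order, the 8, 5, 5 and 14 above among them.

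For donor against recipient the count changed with library size only (5), no gene filter (18), no UMI minimum (1), at least 10 cells per sum (3), thinning (2), no replicate block (1), patients as the units (4), patient A alone (0), CD4 cells only (0), CD8 cells only (3), CD69+CD103+ cells only (0), genes with at least 30 UMIs (27), no pseudogenes or clone-named features (4) and TMM from more genes (1). In CD69+ cells it changed with no gene filter (15), no UMI minimum (2), thinning (0), sums over both classes (8), no replicate block (3), patient A alone (0), CD4 cells only (3), CD8 cells only (2), genes with at least 30 UMIs (14), no pseudogenes or clone-named features (3), TMM from more genes (0) and intermediate cells as positive (8).

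For CD69 it changed with no gene filter (8), thinning (1), sums over both classes (10), patients as the units (0), patient A alone (0), CD8 cells only (0), genes with at least 30 UMIs (9), TMM from more genes (10) and intermediate cells as positive (9). For CD103 it changed with no gene filter (4), sums over both classes (2) and genes with at least 30 UMIs (2). CD103 with at least 10 cells per sum, and in patient A alone, could not be fitted. For CD8 against CD4 it changed with library size only (8), no gene filter (25), no UMI minimum (6), thinning (1), no replicate block (9), patients as the units (6), patient A alone (3), genes with at least 30 UMIs (26), no pseudogenes or clone-named features (7) and TMM from more genes (34). Thinning, single patients or classes, and larger cell minimums use fewer UMIs or cells, and the 30-UMI fit and the unfiltered fit test more genes. For the other settings the cause was not tested. Plates pair the sums by design, and the plate block left the counts for CD69 (4 without it) and CD103 (0) within 1.5 times.

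Leaving out each plate gave 4 to 8, 1 to 6, 1 to 7, 0 to 0 and 6 to 17 genes, lowest without patient B's plate 1, 3 and 4 in the first 3 comparisons and without plate 1, 3 or 4 in the last. The lists past camera were 11, with 6 under an estimated correlation, 24 under fry and 6 as summed UMIs.

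The CD69+ share reversed in CD8 cells (-1.50 points) and passed with intermediate cells as positive (15.5). The CD103+ share no longer passed with no UMI minimum (9.76), in CD4 cells (1.08, where 4 plates cannot go below 0.125) and in CD8 cells (0.18). Without each plate the ranges were 7.25 to 13.1 and 9.86 to 18.6 points. The 26 gene values had 680 values under alternatives. Of these 439 kept their direction and side of the threshold, 240 kept the direction without passing, and CD52 reversed without a gene filter (-0.0147); the cause was not tested. GZMB in donor cells ranged from 0.57 to 1.49 (adjusted p from 0.00014 to 0.85). With a median of 1315 UMIs per cell, genes such as S1PR1, KLF2 and CD4 were out of reach.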

Other observations

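The comparisons of cells with no class with CD4 and with CD8 cells were chosen after their marker levels were seen. The test for gamma-delta T cells was set out before its result, and the values of TRDC and TRAC were added after it.

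The 164 cells with an origin but no CD4 or CD8 class resembled CD8 cells in their transcripts more than CD4 cells. They held 222 CPM of CD8A (95% Poisson interval 167 to 291), 206 of CD8B (152 to 272) and 8.39 of CD4 (1.02 to 30.3). CD8 cells held 365, 212 and 5.31, and CD4 cells 64.3, 26.3 and 52.6. Against CD4 cells, their summed CD8 T cell markers were higher by log2 2.37 ± 0.36 (edgeR adjusted p = 6.4e-06) and CD4 T cell markers lower (-2.73 ± 0.51, adjusted p = 0.00010). Cytotoxicity genes (0.95 ± 0.13, adjusted p = 3.2e-06), cytokines and chemokines (0.66 ± 0.13, adjusted p = 0.00014) and mitochondrial transcripts (0.46 ± 0.07, adjusted p = 3.2e-06) were higher too. Against CD8 cells none of these lists passed in edgeR: CD8 T cell markers stood at -0.41 ± 0.19 (adjusted p = 0.24) and cytotoxicity genes at -0.09 ± 0.13 (adjusted p = 0.69). Their median depth was 1376.5 UMIs, against 1380.5 in CD4 and 1272 in CD8 cells.

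Set against all classed cells, the cells with no class had 0 of 462 genes past the edgeR threshold, with 31 at an unadjusted p under 0.05. The type 17 genes were lower as a sum (-0.91 ± 0.26, edgeR adjusted p = 0.022), but not against CD4 cells (-0.49 ± 0.31, adjusted p = 0.33) or CD8 cells (-0.60 ± 0.29, adjusted p = 0.24) alone. The fit of 5907 genes with at least 30 UMIs called 3 genes, all lower. RORA, chosen after its values were seen, was among them (-1.22 ± 0.20, edgeR adjusted p = 0.00011). As a member of the type 17 list it also enters that sum, so the 2 results are not separate. A hypothesis that gamma-delta T cells, which often lack CD4 and CD8, are among this group was tested on TRDC, TRGC1 and TRGC2. Their summed UMIs differed from those of classed cells by log2 0.11 ± 0.31 (37 against 171 UMIs, edgeR adjusted p = 0.88). The bound set beforehand, below 2-fold, was wrong for this sum, since TRGC1 and TRGC2 of CD8 cells gave 142 of the 171 UMIs. TRDC alone, looked at afterwards, gave 5 against 9 UMIs, 21.0 against 9.92 CPM (log2 ratio 1.08, 95% interval -0.84 to 2.81). These counts are too few to decide on a small share. TRAC, the constant gene of the alpha-beta receptor, differed from CD8 cells by log2 -0.0772 ± 0.153 within plates and was seen in 122 of the 164 cells. This argues against gamma-delta cells as most of the group, if such cells hold little TRAC RNA, and a smaller share stays open.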
